A study of Arabidopsis thaliana with 20 samples.

How the data were processed

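RNA was measured in 20 Arabidopsis thaliana libraries, 2 per combination of 2 tissues and 5 genotypes. Per the labels' protocols, plants grew at 20 degrees C with 16 h of light, RNA of 300 to 400 meiocyte masses or of 4 to 5 seedlings was extracted per replicate, and polyadenylated RNA was turned into libraries by version 2 of the TruSeq RNA kit. That kit does not record the strand, so reads from overlapping genes on opposite strands cannot be separated by strand, and selection for poly(A) tails leaves organellar transcripts poorly sampled. The deposited values are raw counts per gene or TE, and the authors named cutadapt 3.4, STAR 2.7.9a, featureCounts 2.0.0 and DESeq2 1.30.1 on TAIR10, per the submitters' processing notes. Settings for strand, reads with several hits and overlapping genes are not given in the sources used here, and they decide how genes with near-identical copies and TEs are counted. Each file holds 58844 features: 27445 nuclear, 88 chloroplast and 122 mitochondrial genes and 31189 TEs. Samples were grouped by title. The samples titled pol2a-2 carry the genotype label pol2a-1, so an alternative joined both as 1 group of 4. The numbers in the titles named replicates and did not pair them.

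Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. The 10 libraries of a tissue entered 1 fit with a coefficient per genotype, after filterByExpr (minimum count 10; 19739 genes and 1475 TEs kept in meiocytes, 20549 and 1748 in seedlings) and TMM scaling. Comparisons used the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all features, and a gene with adjusted p under 0.05 was called. Each mutant was compared with WT, the triple mutant with pol2a-1 and with suvh2suvh9, and pol2a-2 with pol2a-1. Non-additivity was the effect of the triple mutant minus those of pol2a-1 and suvh2suvh9. The tissue difference was the interaction of tissue and genotype in a fit of all 20 libraries. The p values measure only the spread between these samples. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts a ratio with its 95% interval is given, and floors and intervals cover counting error only.

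Gene lists were fixed before the data were examined, as were the comparisons, the named-gene rule and most alternatives. They hold the 3 targeted genes, 24 DNA damage response genes, 41 meiosis genes, 6 of 7 genes silenced by DNA methylation, 36 of 39 silencing machinery genes, 22 DNA replication genes, 21 Polycomb and flowering targets, 18 of 19 tapetum, 10 photosynthesis, 6 of 7 pollen, 7 root, 13 immune response, 13 of 14 heat and wound stress and 12 clock genes, the numbers being those found by locus. Lists with at least 5 tested members were tested, two-sided, with camera at a preset correlation of 0.01, adjusted over the lists of all comparisons in a tissue. Members were called over all genes and also adjusted over the list alone. The rule named, per comparison with WT, the 6 largest rises and 6 largest falls among called genes with a mean of at least 1 CPM and both libraries beyond both WT libraries, the targeted genes, at most 4 called members of each list and genes called in all 4 mutants. Because many of these consisted of repeated sequence, the 3 largest per direction outside it were added after seeing the data. Of 112 named genes with annotated exons, 27 overlapped another gene and 18 over more than 10% of their exons.

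Repeated sequence was measured in the reference TAIR10.1, as the percent of 100-base windows of a gene's exons found more than once in the genome. A gene counted as repeated from 10%. Alternatives fixed beforehand were DESeq2 size factors, no filter, the DESeq2 1.42.0 Wald test, only the groups compared in the fit, all 20 libraries in 1 fit, a replicate block, organellar genes left out, each library left out, an estimated correlation and fry for lists, and a 2-fold limit for shared genes. Added after seeing the data were leaving out repeated-sequence and organellar genes, an offset for each library's smooth trend with gene length, and leaving out 2 seedling libraries together. Shared controls were assessed with 20 simulated draws per tissue of unchanged groups against the same WT libraries. In simulated counts with 100 changed genes per fold size, the comparison of pol2a-1 with WT recovered 28% of 2-fold and 89% of 4-fold changes in meiocytes and 39% and 97% in seedlings, with 5.65% and 3.55% of calls on unchanged features. These fits held 20538 and 21906 features.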

Results

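RNA of 20 libraries was sequenced, 2 for each of 10 groups that crossed 2 tissues with 5 genotypes. Meiocytes, the cells that enter meiosis, came from floral buds of stages 9 to 10, and the seedlings were 20 days old. Beside wild type (WT), the genotypes were pol2a-1 and pol2a-2, mutants of POL2A, which encodes the catalytic subunit of DNA polymerase epsilon. The double mutant suvh2suvh9 lacks SUVH2 and SUVH9, proteins that recruit the machinery of RNA-directed DNA methylation, and pol2a-1suvh2suvh9 (the triple mutant) combines the 3 mutations. Total counts of replicates 1 and 2 in meiocytes, in units of 1e6, were 16.9 and 20.9 in WT, 18.0 and 18.17 in pol2a-1, 11.9 and 13.6 in pol2a-2, 19.6 and 16.8 in suvh2suvh9 and 17.2 and 16.9 in the triple mutant. In seedlings they were 34.5 and 26.8 in WT, 15.1 and 11.9 in pol2a-1, 14.6 and 23.6 in pol2a-2, 27.3 and 26.7 in suvh2suvh9 and 27.7 and 23.0 in the triple mutant. Levels are CPM (counts per 1e6 counts of a library) as mean ± SD (n = 2), changes are log2 fold changes ± standard error (n = 2 per group), and adjusted p values come from edgeR's two-sided quasi-likelihood test with Benjamini-Hochberg adjustment.

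The targeted genes were read first, as a check of the labels. SUVH9 stood at 10.2 ± 4.74 CPM in WT meiocytes and at 0.0261 ± 0.0369 and 0.0275 ± 0.0390 CPM in suvh2suvh9 and triple mutant meiocytes, lower 352-fold with a counting interval of 62.8 to 13947 (adjusted p 0.00375) and 359.6-fold with a counting interval of 64.1 to 14242 (adjusted p 0.00361). In seedlings it fell 35.5-fold (log2 -5.15 ± 0.24, adjusted p 1.0e-06) in suvh2suvh9 and 52.6-fold (log2 -5.72 ± 0.25, adjusted p 6.7e-07) in the triple mutant. SUVH2 fell 4.33-fold (log2 -2.11 ± 0.25, adjusted p 0.00639) in triple mutant meiocytes, 2.51-fold (log2 -1.33 ± 0.22, adjusted p 0.00482) in suvh2suvh9 seedlings and 2.23-fold (log2 -1.15 ± 0.22, adjusted p 0.00807) in triple mutant seedlings. In suvh2suvh9 meiocytes its difference did not pass the test (log2 -1.56 ± 0.25, adjusted p 0.102). POL2A fell 2.21-fold (log2 -1.14 ± 0.20, adjusted p 0.0176) in pol2a-1 meiocytes and 3.28-fold (log2 -1.71 ± 0.20, adjusted p 0.00639) in triple mutant meiocytes, from 206 ± 46.7 CPM in WT. Leaving out 1 library ended the pol2a-1 call, at adjusted p 0.110 without WT replicate 1, 0.198 without pol2a-1 replicate 1 and 0.262 without pol2a-1 replicate 2. In the triple mutant it ended the calls of POL2A and SUVH2 without triple mutant replicate 2 (adjusted p 0.140 to 0.140) in meiocytes and of SUVH2 without either triple mutant replicate or WT replicate 2 (adjusted p 0.0538 to 0.0817) in seedlings, and in suvh2suvh9 seedlings of SUVH2 without suvh2suvh9 replicate 2 (adjusted p 0.0516). In pol2a-2 meiocytes POL2A stood at 151 ± 6.53 CPM (log2 -0.44 ± 0.20, adjusted p 0.461).

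POL2A passed no test in seedlings. It stood at 47.1 and 41.5 CPM in the WT libraries, 28.7 and 30.4 in pol2a-1 (log2 -0.58 ± 0.27, adjusted p 0.328) and 37.2 and 40.2 in the triple mutant (log2 -0.20 ± 0.26, adjusted p 0.677). The seedling libraries titled pol2a-2 stood at 29.9 and 60.9 CPM, replicate 2 above both WT libraries (log2 0.04 ± 0.26, adjusted p 0.947). What each allele changes in the gene is not given in the sources used here, so the count over the whole gene need not fall. POL2A spans 2588854 to 2606892 on chromosome 1, and exons of its opposite-strand neighbours cover 24.4% of its exonic bases.

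**Figure D1:**
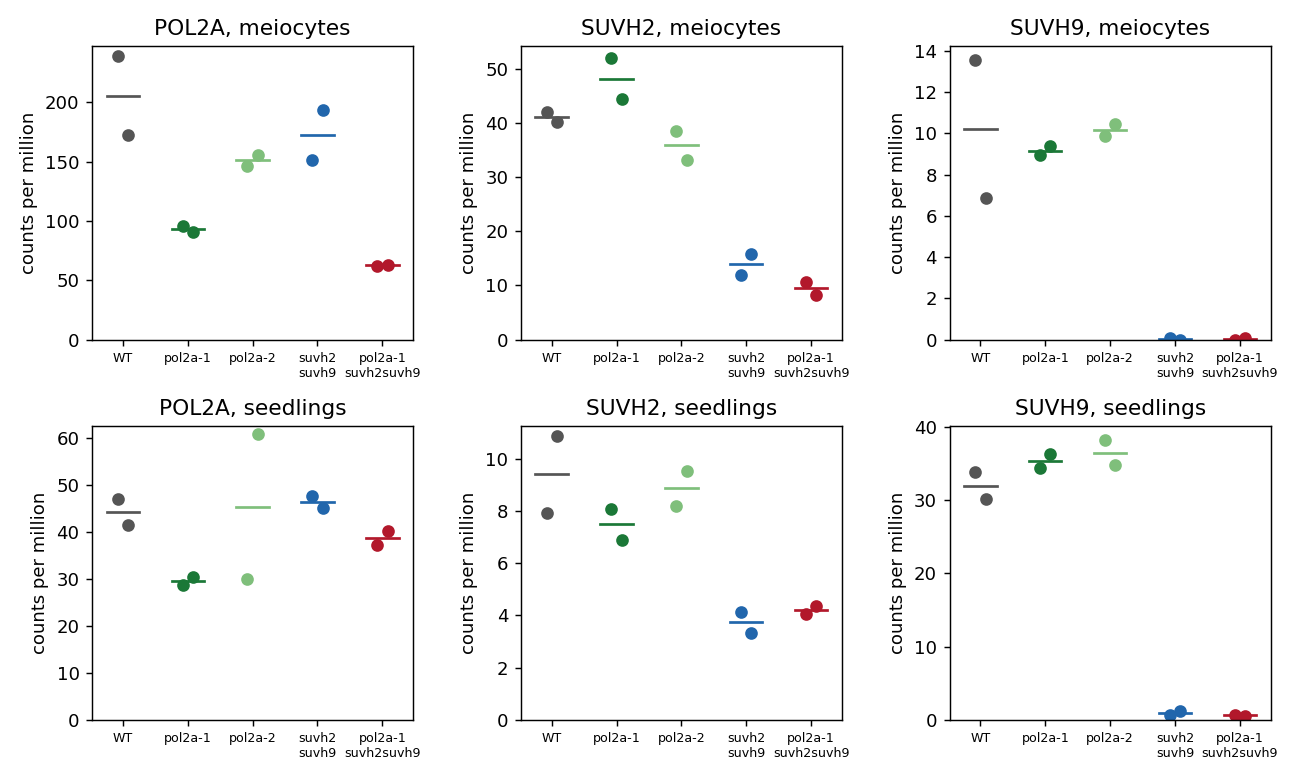
CPM of POL2A, SUVH2 and SUVH9 in each of the 20 libraries (points) with the group mean (line), meiocytes above and seedlings below. SUVH9 lies near 0 in suvh2suvh9 and the triple mutant in both tissues, and seedling pol2a-2 replicate 2 has the highest seedling POL2A value (60.9).

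Genes with near-identical copies split the libraries into sets that followed different genotypes in the 2 tissues. Of 182 tested genes in meiocytes with at least 50% repeated exonic sequence, 55 to 56 had 0 counts in the WT libraries, 5 in pol2a-1, 1 to 2 in pol2a-2, 57 to 64 in suvh2suvh9 and 56 to 62 in the triple mutant. Of 141 such genes in seedlings the numbers were 30 to 33, 36 to 37, 32 to 38, 1 and 0 to 1. Chloroplast genes took 2.11 to 2.42% of counts in seedling WT, pol2a-1 and pol2a-2 and 0.0215 to 0.0443% in suvh2suvh9 and the triple mutant. Organellar genes and genes with at least 10% repeated sequence are uncertain across these sets and are counted apart below.

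**Figure D2:**
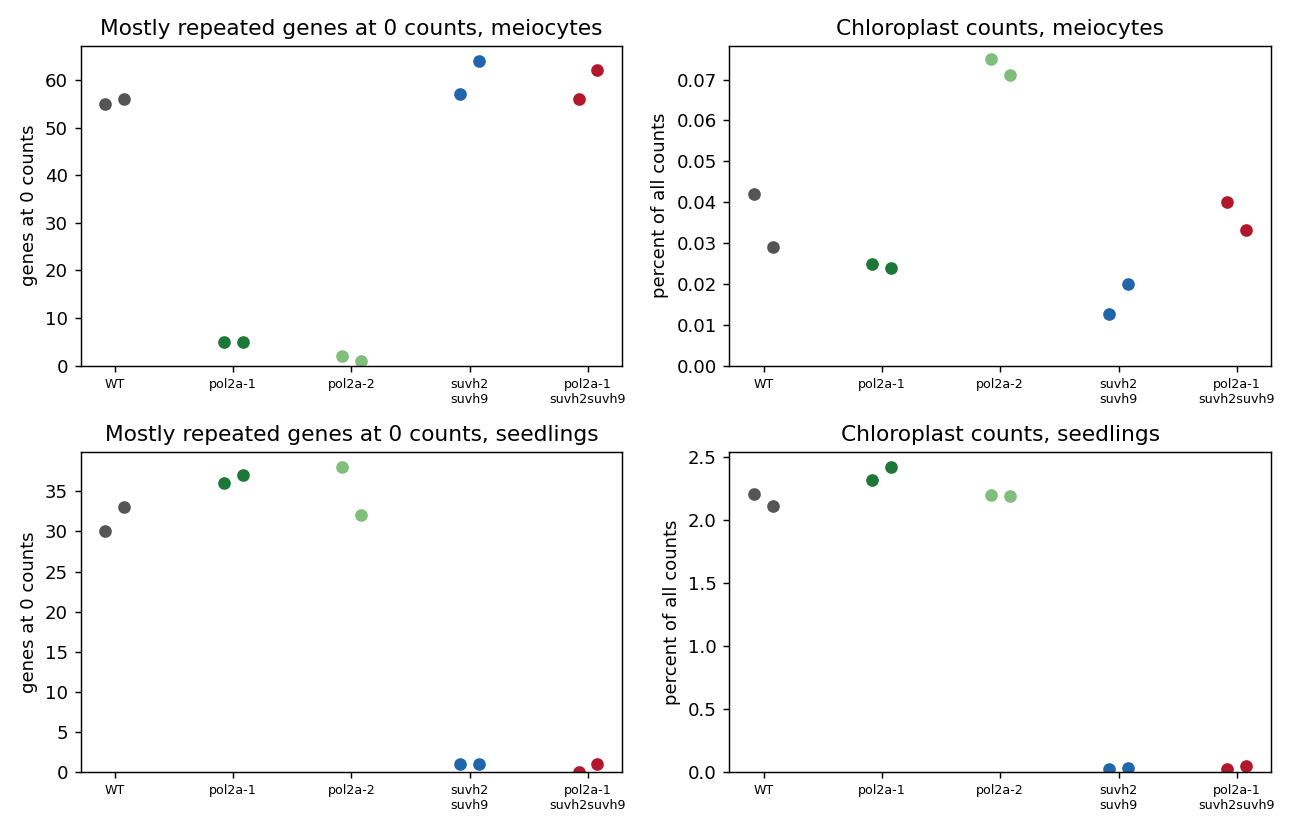
Left, tested genes with at least 50% repeated exonic sequence that had 0 counts, and right, percent of all counts on chloroplast genes, per library (points) for meiocytes above and seedlings below. Meiocyte pol2a-1 and pol2a-2 and seedling suvh2suvh9 and triple mutant libraries have 0 to 5 such genes at 0 counts, and the other libraries 30 to 64.

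The meiocyte comparison of pol2a-1 with WT asked which transcripts change. Outside repeated sequence, in genes chosen after their values were seen, AT2G11035 (at least 316-fold, adjusted p 1.4e-04), AT1G35320 (at least 86.0-fold, adjusted p 1.6e-04) and AT1G67020 (log2 -7.15 ± 0.74, adjusted p 3.3e-04) fell and AT1G63540 (at least 147-fold, adjusted p 0.00358), AT2G10615 (at least 122-fold, adjusted p 0.00730) and AT2G05915 (log2 7.89 ± 0.84, adjusted p 0.00102) rose. AT2G13965 (log2 -6.19 ± 0.79, adjusted p 0.00147), the kinase gene AT4G01595 (52.3-fold with a counting interval of 14.2 to 438, adjusted p 0.00506) and AT2G10931 (log2 -5.40 ± 0.76, adjusted p 0.00348) were further large falls. Opposite-strand genes cover 60.9%, 37.2%, 100%, 100% and 75.7% of the exons of AT2G11035, AT2G10615, AT2G05915, AT2G13965 and AT4G01595. The 6 largest rises, AT4G09310, AT1G58983, AT5G50630, AT5G50550, AT1G25055 and LpxC5, at least 359- to 4269.9-fold, were all in genes that consist of repeated sequence. Leaving out 1 library ended the calls of AT1G63540 without pol2a-1 replicate 1, AT2G10615 without either pol2a-1 replicate and AT4G01595 without pol2a-1 replicate 2 (adjusted p 0.0501 to 0.116).

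In all, 84 genes were higher and 31 lower in pol2a-1 meiocytes among 19739 tested. Of the higher genes 50 had repeated sequence, 12 were organellar and 22 were others, against 1, 0 and 30 of the lower. With the former classes left out, 16 genes were higher and 23 lower. With 1 library left out the higher genes numbered 154 without WT replicate 2. The lower genes numbered 19 and 85 without WT replicates 1 and 2 and 12 and 11 without pol2a-1 replicates 1 and 2. No list fixed beforehand had a called member apart from POL2A. Silencing machinery genes moved down as a group (27 of 36 negative, median -0.26, camera adjusted p 0.0114). Polycomb and flowering targets (camera adjusted p 0.0147), tapetum genes (camera adjusted p 0.0244) and photosynthesis genes (camera adjusted p 0.0103) moved up. These 4 lists had adjusted p 0.504 to 0.649 with an estimated correlation. Genes of at least 4000 bases had a median log2 fold change of -0.14 and those under 1000 bases of 0.18, and with this length trend removed silencing and tapetum genes no longer passed (camera adjusted p 0.204 and 0.0767) and DNA damage response genes did (0.0376). Adjusted over the list alone, 3 DNA damage response genes, 2 photosynthesis genes and 1 Polycomb target were higher and 1 silencing gene lower, and 8 other tested lists had camera adjusted p 0.118 to 0.954.

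The comparison of pol2a-2 asked the same of the second allele. In meiocytes titled pol2a-2, MS2 rose 312-fold with a counting interval of 55.5 to 12394 (adjusted p 0.00871). It is a fatty acyl reductase gene of the tapetum that serves the pollen wall. Outside repeated sequence, and chosen after their values were seen, the carbonic anhydrase gene ACA5 (at least 88.3-fold, adjusted p 0.0378), AT1G47980 (at least 70.5-fold, adjusted p 0.0378) and the chitinase gene AT2G43620 (at least 26.2-fold, adjusted p 0.0351) rose. The 6 largest falls were all on chromosome 1: AT1G10000 (at least 43.1-fold, adjusted p 4.7e-04), the receptor kinase gene AT1G11280 (at least 17.61-fold, adjusted p 0.0118), the mitochondrial RNA processing factor gene RPF1 (log2 -4.21 ± 0.76, adjusted p 0.0234), AT1G10980 (log2 -2.43 ± 0.26, adjusted p 3.2e-04), PAI1 of tryptophan synthesis (log2 -2.30 ± 0.35, adjusted p 0.00673) and the myosin gene XIA (log2 -1.78 ± 0.20, adjusted p 4.8e-04). PAI1 is uncertain, with 46.2% repeated sequence. The largest rises were again AT4G09310, AT1G25055, AT1G58983, AT5G50630 and LpxC5, beside the mitochondrial ATMG00220. Leaving out 1 library ended the calls of MS2, ACA5 and AT1G47980 without either WT replicate or pol2a-2 replicate 1, AT2G43620 without either WT or pol2a-2 replicate or triple mutant replicate 2, AT1G11280 without pol2a-2 replicate 1, RPF1 without either WT replicate and PAI1 without WT replicate 2 or pol2a-2 replicate 1 (adjusted p 0.0519 to 0.496).

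Tapetum genes, of the anther layer around the meiocytes, were higher as a group in pol2a-2: 16 of 17 were positive, 1 passed over all genes and 10 adjusted over the list alone (median 1.12, camera adjusted p 3.8e-07). Replicate 1 stood apart, with list means of 1.78 and 0.67 log2 from WT in replicates 1 and 2. Photosynthesis genes (all 10 positive, median 0.79, camera adjusted p 3.4e-05) and Polycomb and flowering targets (all 14, median 1.35, camera adjusted p 4.5e-05) moved the same way. All these lists rose by camera in every meiocyte mutant, against the same WT libraries. Meiosis genes (26 of 41 negative, camera adjusted p 0.0107) and silencing genes (camera adjusted p 0.0152) moved down, by list means of -0.23 and -0.04 and of -0.19 and -0.08. The latter 2 no longer passed with the length trend removed (camera adjusted p 0.233 and 0.718), long and short genes having medians of -0.31 and 0.08. These 5 lists had adjusted p 0.504 to 0.620 with an estimated correlation, and 7 other tested lists had camera adjusted p 0.171 to 0.977. In all 114 genes were higher and 14 lower, the higher with 62 of repeated sequence, 33 organellar and 19 others and the lower with 13 others. With the former classes left out, 3 were higher and 3 lower. Higher genes numbered 68 without WT replicate 2. Lower genes numbered 8 and 7 without pol2a-1 replicates 1 and 2, 9 and 30 without pol2a-2 replicates 1 and 2 and 8 without either triple mutant replicate.

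Both pol2a groups shared 60 higher genes, where 0.485 were expected from list sizes. With repeated-sequence and organellar genes left out they shared 0 by edgeR. No lower gene was shared. Their fold changes correlated across genes, which are not replicates, at r 0.28 against 0.50 in the simulations, and the covariance differed from the simulated by -0.00316. The WT libraries are too few to split, so part of any excess may come from sharing them. Directly compared, 92 genes differed between pol2a-2 and pol2a-1 (65 higher and 27 lower in pol2a-2), of which 10 and 3 had repeated sequence and 22 and 0 were organellar. This number was 141 without either WT replicate, 22 without either pol2a-1 replicate, 255 without pol2a-2 replicate 2 and 140 without suvh2suvh9 replicate 2.

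The suvh2suvh9 meiocytes were compared with WT. SUVH9 was the 1 gene called in the fit of 10 libraries. No gene was called higher, with 602 higher and 438 lower at an unadjusted p under 0.05. DESeq2 called 68 and 112. With edgeR, the groups compared alone gave 3 and 77 and all 20 libraries 108 and 50. No transposable element (TE) was called, with 35 and 28 unadjusted and 4 and 3 by DESeq2. Tapetum genes moved up as a group (13 of 17 positive, 5 higher adjusted over the list alone, camera adjusted p 2.2e-08), as did Polycomb and flowering targets (camera adjusted p 4.9e-06), photosynthesis genes (camera adjusted p 0.00970, list means 0.33 and 0.50 against 0.40 and -0.40 in WT, so this rise rests on WT replicate 2) and heat and wound genes (camera adjusted p 0.0240, list means 0.20 and 0.66 in replicates 1 and 2). DNA replication genes moved down, 19 of 22 negative (median -0.16, camera adjusted p 0.00970). These 5 lists had adjusted p 0.504 to 0.578 with an estimated correlation. Of 5 tested genes silenced by DNA methylation, 2 were higher adjusted over the list alone (camera adjusted p 0.0709), and 6 other tested lists had camera adjusted p 0.0750 to 0.976. Higher genes numbered 1 without WT replicate 1, 8 and 9 without pol2a-2 replicates 1 and 2, 15 without suvh2suvh9 replicate 2 and 4 without either triple mutant replicate. Lower genes numbered 4 without WT replicate 2, 23 and 26 without pol2a-2 replicates 1 and 2, 2 without either suvh2suvh9 replicate and 54 and 57 without triple mutant replicates 1 and 2.

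Triple mutant meiocytes were compared with WT to ask what changes with all 3 mutations. Beside the 3 targeted genes, AT1G08270, a neighbour of POL2A that shares 36.4% of its exonic bases with it, fell 7.36-fold (log2 -2.88 ± 0.35, adjusted p 0.00639). Rises included the lipid transfer gene LTP6 (log2 2.18 ± 0.23, adjusted p 0.00639), the receptor kinase gene PERK13 (log2 2.97 ± 0.34, adjusted p 0.00639), the arabinogalactan gene AGP31 (log2 2.20 ± 0.34, adjusted p 0.0498), the defence peptide gene THI2.1 (log2 2.56 ± 0.40, adjusted p 0.0498), the transporter gene ABCA10 (log2 4.19 ± 0.65, adjusted p 0.0498) and AT3G02640 (log2 2.89 ± 0.39, adjusted p 0.0199). Photosynthesis genes moved up as a group, all 10 positive and 9 higher adjusted over the list alone (median 1.25, list means 1.79 and 0.86 in replicates 1 and 2, camera adjusted p 8.4e-10). So did tapetum genes (10 of 17 adjusted over the list alone, median 1.34, or 1.11 with members at the floor set to their bound, camera adjusted p 2.1e-07) and Polycomb and flowering targets (6 of 14, median 1.44, camera adjusted p 7.9e-07). Meiosis (camera adjusted p 0.0114), silencing (camera adjusted p 0.00925) and replication genes (camera adjusted p 0.0246) moved down, and none of these passed with the length trend removed (camera adjusted p 0.239, 0.251 and 0.248; long and short genes had medians of -0.30 and -0.01). These 6 lists had adjusted p 0.504 to 0.620 with an estimated correlation, and 6 other tested lists had camera adjusted p 0.0810 to 0.902. Leaving out 1 library ended the calls of PERK13 without WT replicate 1, AGP31 and THI2.1 without either WT, pol2a-1 or triple mutant replicate, ABCA10 without either WT or pol2a-1 replicate or triple mutant replicate 2 and AT3G02640 without either WT replicate or triple mutant replicate 2 (adjusted p 0.0543 to 0.226).

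In all 8 genes were higher and 4 lower in triple mutant meiocytes. DESeq2 gave 409 and 78, and fitting only the groups compared 1 and 0. Higher genes numbered 4 without WT replicate 2, 4 without either pol2a-1 replicate, 35 and 47 without pol2a-2 replicates 1 and 2, 28 without either suvh2suvh9 replicate and 3 without triple mutant replicate 2. Lower genes numbered 10 without WT replicate 2, 7 without pol2a-2 replicate 2 and 17 and 2 without triple mutant replicates 1 and 2. The triple mutant differed from pol2a-1 in 127 genes, 40 higher and 87 lower, of which 56 lower ones had repeated sequence and 12 were organellar. This number was 3752 with only the groups compared, 79 and 80 without pol2a-1 replicates 1 and 2, 196 and 208 without pol2a-2 replicates 1 and 2, 234 and 238 without suvh2suvh9 replicates 1 and 2 and 81 without triple mutant replicate 2. It differed from suvh2suvh9 in 8 genes, with 5 of the 6 higher ones organellar, in 1 with organellar genes left out, or in 15 without either pol2a-2 replicate, 3 without suvh2suvh9 replicate 2 and 1 without triple mutant replicate 1. The effects of pol2a-1 and suvh2suvh9 did not add up in 35 genes, and in 7 with repeated-sequence and organellar genes left out. Leaving out 1 library gave 22 without WT replicate 1, 18 and 16 without pol2a-1 replicates 1 and 2, 22 without suvh2suvh9 replicate 2 and 16 without triple mutant replicate 1.

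In seedlings, the comparison of pol2a-1 with WT asked what POL2A affects outside meiosis. AT1G75945 rose from 0.0565 ± 0.0798 to 5.79 ± 1.17 CPM, 120.2-fold with a counting interval of 40.4 to 589 (adjusted p 0.0178). The zinc finger genes AT5G22920 (log2 1.55 ± 0.16, adjusted p 0.0217) and ATCTH (log2 1.17 ± 0.13, adjusted p 0.0290) rose and the chaperone gene AT3G14200 fell (log2 -1.25 ± 0.14, adjusted p 0.0290). AT3G14200 was the 1 gene lower in all 4 seedling mutants, by 0.85, 1.41 and 1.31 on the log2 scale in the libraries titled pol2a-2, suvh2suvh9 and the triple mutant. Immune response genes moved down as a group (11 of 13 negative, 4 lower adjusted over the list alone, median -1.03, camera adjusted p 9.4e-05), and so did heat and wound (camera adjusted p 0.00161), clock (camera adjusted p 0.00161) and silencing genes (camera adjusted p 0.00174). Polycomb and flowering targets (17 of 19 positive, median 0.51, camera adjusted p 6.0e-05), tapetum (camera adjusted p 0.0193) and DNA damage response genes (4 of 24 adjusted over the list alone, median 0.26, camera adjusted p 0.0189) were called up by camera. In the latter 2 lists the replicates went opposite ways, with list means of -0.27 and 2.03 log2 from WT for tapetum and 0.59 and -0.19 for DNA damage response genes in replicates 1 and 2, so each rise rests on 1 library. The means were also uneven for immune (-0.56 and -1.22, with 0.38 and -0.38 in WT), silencing (-0.18 and -0.55) and Polycomb and flowering genes (0.27 and 0.65). These 7 lists had adjusted p 0.445 to 0.748 with an estimated correlation, and 4 other tested lists had camera adjusted p 0.525 to 0.955.

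The pol2a-1 seedlings had 3 higher genes and 1 lower among 20549 tested, and 57 and 67 by DESeq2 and 341 and 1040 with only the groups compared. Higher genes numbered 0 and 1 without WT replicates 1 and 2, 0 without either pol2a-1 replicate, 288 and 301 without pol2a-2 replicates 1 and 2, 1 without either suvh2suvh9 replicate and 1 without either triple mutant replicate. Lower genes numbered 0 without WT replicate 1, 0 without either pol2a-1 replicate, 745 and 721 without pol2a-2 replicates 1 and 2, 0 without either suvh2suvh9 replicate and 0 without either triple mutant replicate. Genes of at least 4000 bases had a median log2 fold change of -0.53 and those under 1000 bases of 0.26, and silencing genes no longer passed with this trend removed (camera adjusted p 0.546). None of the calls held throughout: leaving out 1 library ended those of AT1G75945 without either pol2a-1 or triple mutant replicate or WT replicate 1, AT5G22920 without either WT, pol2a-1 or suvh2suvh9 replicate and ATCTH and AT3G14200 without either WT, pol2a-1, suvh2suvh9 or triple mutant replicate (adjusted p 0.0501 to 0.654).

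The seedling libraries titled pol2a-2 were compared with WT to ask what the second allele changes outside meiosis. DNA damage response genes were higher. XRI1, a gene induced by X-rays, rose 7.49-fold (log2 2.91 ± 0.15, adjusted p 3.5e-05), the ribonucleotide reductase gene TSO2 rose 6.88-fold (log2 2.78 ± 0.21, adjusted p 4.6e-04), the thymidine kinase gene TK1A 9.28-fold (log2 3.21 ± 0.28, adjusted p 8.4e-04), and the G2-phase cyclin gene CYCB1;1 5.19-fold (log2 2.38 ± 0.21, adjusted p 8.7e-04). The cell-cycle inhibitor gene SMR7 (log2 6.71 ± 0.84, adjusted p 0.00429) and the transcription factor gene NAC085 (at least 67.8-fold, adjusted p 0.00409) were among the largest rises. Of 24 tested genes of the list 13 rose over all genes and 17 adjusted over the list alone, and none fell (median 1.98, camera adjusted p 3.4e-38, and adjusted p 0.117 with an estimated correlation). Among meiosis genes 7 of 38 rose and 10 adjusted over the list alone (list means 0.24 and 0.65 in replicates 1 and 2, camera adjusted p 5.5e-07, and adjusted p 0.378 with an estimated correlation), with the strand exchange gene DMC1 (log2 2.05 ± 0.16, adjusted p 5.2e-04), its cofactors HOP2 (log2 1.89 ± 0.22, adjusted p 0.00301) and MND1 (log2 1.68 ± 0.21, adjusted p 0.00429), and HEI10 (log2 4.02 ± 0.45, adjusted p 0.00269). HEI10 and MRD1, a gene silenced by DNA methylation that rose (log2 6.39 ± 0.66, adjusted p 0.00178), overlap each other on opposite strands, and other genes cover 41.3% and 89.8% of their exons, so unstranded counts cannot tell them apart. With 1 library left out, called genes numbered 5 without WT replicate 1 to 14 for the DNA damage response and 1 without WT replicate 1 to 7 for meiosis.

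The floral genes SEP3 (log2 2.52 ± 0.28, adjusted p 0.00276) and SEP1 (log2 1.56 ± 0.28, adjusted p 0.0236) rose in the seedling libraries titled pol2a-2. The flowering repressor FLC fell (log2 -3.17 ± 0.43, adjusted p 0.00664). Opposite-strand genes cover 68.1% of FLC and 35.8% of SEP1 exons. Of 19 Polycomb and flowering targets 4 rose and 1 fell, and 9 and 1 adjusted over the list alone (camera adjusted p 1.1e-05). Of 12 clock genes 4 fell, RVE8 the most (log2 -1.03 ± 0.16, adjusted p 0.0132; list means -0.65 and -0.30, camera adjusted p 5.5e-04), and 2 of 21 replication genes rose (list means 0.09 and 0.42, camera adjusted p 0.00849). Immune genes were all negative without a call (camera adjusted p 0.00367). These 4 lists had adjusted p 0.423 to 0.748 with an estimated correlation. With 1 library left out, called genes numbered 0 without WT replicate 1 to 7 without pol2a-2 replicate 2 for the lower clock genes, 0 without WT replicate 1 to 4 without pol2a-2 replicate 2 for the higher replication and 1 without WT replicate 1 to 4 for the higher Polycomb and flowering genes. The 5 other tested lists had camera adjusted p 0.0561 to 0.778, the genes silenced by DNA methylation with a median of -0.60 and a camera direction of up. Among the largest falls were AT1G12010 (at least 31.4-fold, adjusted p 0.00166) and AT1G11280 (log2 -6.56 ± 0.30, adjusted p 2.5e-05). With 1 library left out, calls ended for SMR7 and SEP1 without either WT replicate and NAC085, HEI10, HOP2, MND1, FLC and RVE8 without WT replicate 1 (adjusted p 0.0505 to 0.152).

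In the libraries titled pol2a-2 361 genes were higher and 193 lower than in WT, 9 and 6 with repeated sequence. They numbered 1 and 3 with both alleles as 1 group, 70 and 55 with only the groups compared and 602 and 368 with the length trend removed. Higher genes numbered 31 and 81 without WT replicates 1 and 2, 1691 without pol2a-2 replicate 2 and 186 and 192 without triple mutant replicates 1 and 2. Lower genes numbered 7 and 31 without WT replicates 1 and 2, 2302 without pol2a-2 replicate 2 and 91 and 93 without triple mutant replicates 1 and 2. Against pol2a-1, 9 of 24 DNA damage response genes were higher and 17 adjusted over the list alone (camera adjusted p 3.4e-46, and adjusted p 0.103 with an estimated correlation), or 3 without pol2a-1 replicate 2 to 15 without pol2a-2 replicate 1 over all genes with 1 library left out. In all 82 genes differed between the alleles, 52 higher and 30 lower in pol2a-2. This number was 8 with only the groups compared, 32 without either WT replicate, 22 and 9 without pol2a-1 replicates 1 and 2, 875 without pol2a-2 replicate 1 and 33 and 40 without triple mutant replicates 1 and 2. Changes of both alleles from WT correlated at r 0.67 (simulated 0.48, covariance 0.0846 above). Part may come from the shared WT libraries or the length trend (long-gene medians -0.53 and -0.45).

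**Figure D3:**
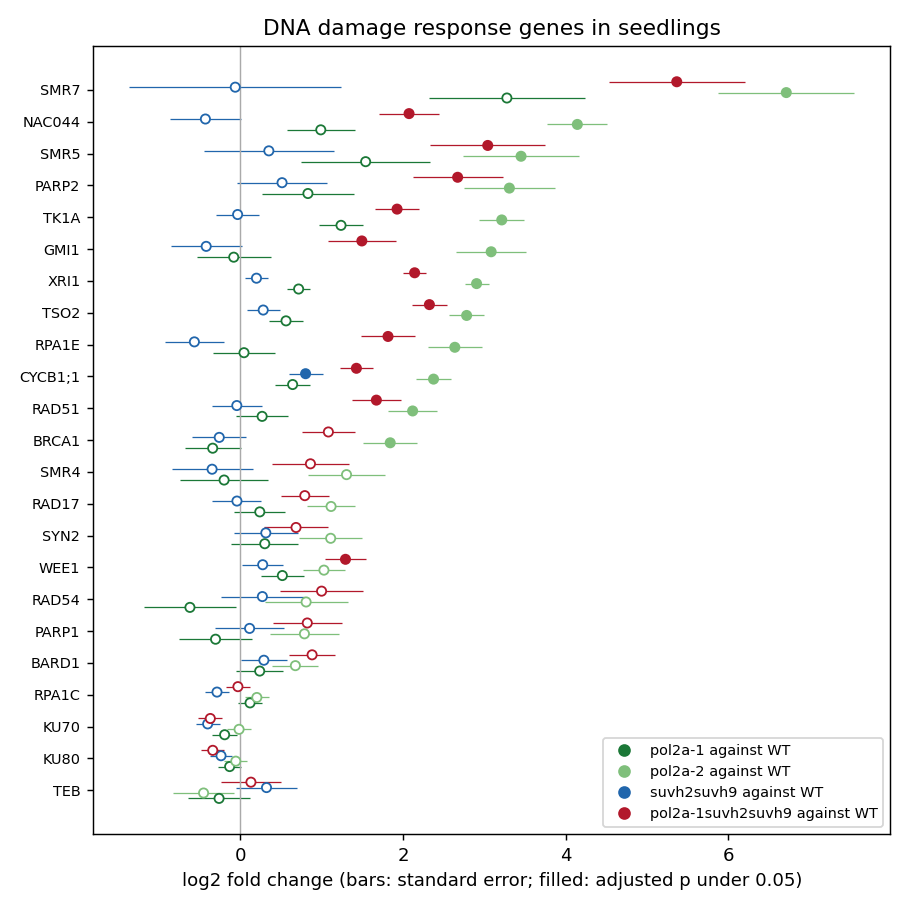
Log2 fold change against WT in seedlings (points, with bars of 1 standard error, filled where the adjusted p is under 0.05) of the DNA damage response genes tested except NAC085, which had 0 counts in WT. SMR7 and XRI1 are filled in pol2a-2 at 6.71 and 2.91, and CYCB1;1 is the 1 filled suvh2suvh9 point.

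Seedlings of suvh2suvh9 were compared with WT, across the library sets. The F-box gene SDC, a known target of RNA-directed DNA methylation, rose 85.1-fold (log2 6.41 ± 0.44, adjusted p 2.5e-05) and MRD1 101-fold (log2 6.66 ± 0.66, adjusted p 3.1e-04), while QQS fell (log2 -1.97 ± 0.47, adjusted p 0.0257), as did the demethylase gene ROS1, known to depend on methylation (log2 -3.16 ± 0.74, adjusted p 0.0238). SDC is uncertain, as an opposite-strand gene covers 80.2% of its exons. Of 5 tested genes silenced by DNA methylation 2 rose and 1 fell. Their median was -0.21 and the camera direction up (camera adjusted p 0.0193, and adjusted p 0.378 with an estimated correlation). The floral genes AG (log2 -3.50 ± 0.48, adjusted p 0.00207) and SEP1 (log2 -3.18 ± 0.39, adjusted p 0.00107) and the flowering activator SOC1 (log2 -0.93 ± 0.14, adjusted p 0.00391) fell, and the homeobox gene KNAT1 rose (log2 1.29 ± 0.20, adjusted p 0.00383). Of 19 Polycomb and flowering targets 9 fell and 1 rose, and 9 and 2 adjusted over the list alone (median -0.93, camera adjusted p 1.3e-04). The defence genes PR1 (log2 -6.88 ± 1.04, adjusted p 0.00322) and PR5 (log2 -2.21 ± 0.25, adjusted p 6.6e-04) were among 5 of 13 immune genes that fell, 7 adjusted over the list alone (camera adjusted p 5.5e-04). These 2 lists had adjusted p 0.445 to 0.557 with an estimated correlation. Without 1 library the lower immune genes numbered 2 without WT replicate 1 to 6. Clock genes went both ways, LHY up (log2 2.04 ± 0.20, adjusted p 2.6e-04) and PRR9 down (log2 -1.31 ± 0.13, adjusted p 3.5e-04, uncertain with 41.5% repeated sequence) (camera adjusted p 0.923), and 7 other tested lists had camera adjusted p 0.129 to 0.955.

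Outside repeated sequence, and chosen after their values were seen, AT1G33850 (at least 53.9-fold, adjusted p 0.00227), its neighbour AT1G33840 (log2 8.02 ± 0.44, adjusted p 3.9e-06) and the kinase gene AT5G24240 (log2 6.97 ± 0.28, adjusted p 4.0e-07) rose in suvh2suvh9 seedlings, and AT5G22430 (319-fold with a counting interval of 56.8 to 12617, adjusted p 2.9e-05) and the beta-amylase gene BAM5 (319-fold with a counting interval of 56.8 to 12617, adjusted p 0.00116) fell. The 6 largest rises, AT1G58983, AT1G59124, AT1G24996, PGLP1, AT1G58684 and AT1G59359, were in genes of repeated sequence and the 6 largest falls in chloroplast genes. In all 1057 genes were higher and 1123 lower, 112 and 12 with repeated sequence and 4 and 86 organellar. With these left out, 942 were higher and 970 lower. Higher genes numbered 300 and 366 without WT replicates 1 and 2, 1786 and 1760 without pol2a-2 replicates 1 and 2 and 679 and 373 without suvh2suvh9 replicates 1 and 2. Lower genes numbered 360 and 508 without WT replicates 1 and 2, 1723 and 1776 without pol2a-2 replicates 1 and 2 and 501 and 395 without suvh2suvh9 replicates 1 and 2. Calls ended for QQS without either WT or suvh2suvh9 replicate and ROS1 without either WT replicate or suvh2suvh9 replicate 2 (adjusted p 0.0611 to 0.159).

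Triple mutant seedlings were compared with WT, again across the sets. XRI1 rose 4.42-fold (log2 2.14 ± 0.14, adjusted p 2.1e-05), TSO2 5.01-fold (log2 2.33 ± 0.21, adjusted p 1.7e-04), TK1A 3.81-fold (log2 1.93 ± 0.27, adjusted p 0.00201) and CYCB1;1 2.69-fold (log2 1.43 ± 0.21, adjusted p 0.00254), and 13 of 24 DNA damage response genes rose (16 rose and 2 fell adjusted over the list alone, median 1.36, camera adjusted p 1.5e-10, and adjusted p 0.378 with an estimated correlation). The flowering signal FT rose from 0.353 ± 0.0741 to 11.6 ± 0.194 CPM, 32.0-fold (log2 5.00 ± 0.47, adjusted p 2.1e-04). SEP3 (log2 1.75 ± 0.28, adjusted p 0.00416) and KNAT1 (log2 1.61 ± 0.20, adjusted p 0.00123) rose and the petal gene AP3 fell (log2 -3.68 ± 0.68, adjusted p 0.00783). Of 19 Polycomb and flowering targets 5 rose and 1 fell (camera adjusted p 0.114). DMC1 (log2 1.01 ± 0.16, adjusted p 0.00414) and HEI10 (log2 3.19 ± 0.44, adjusted p 0.00211) rose among meiosis genes (camera adjusted p 0.0171). SDC (log2 4.43 ± 0.44) and MRD1 (log2 5.42 ± 0.66) rose and QQS fell (log2 -3.94 ± 0.57). PR1 (log2 -5.45 ± 0.91, adjusted p 0.00484) and PR5 (log2 -2.07 ± 0.25, adjusted p 9.4e-04) were among 7 of 13 immune genes that fell, 9 adjusted over the list alone (median -1.74, camera adjusted p 6.7e-05). Cold-responsive COR15A fell (log2 -2.63 ± 0.44, adjusted p 0.00499) in the heat and wound list (list means -1.28 and -0.31 in replicates 1 and 2, camera adjusted p 0.0253). With 1 library left out, called genes numbered 6 without WT replicate 1 to 17 for the higher DNA damage response, 3 without WT replicate 2 to 5 for the higher Polycomb and flowering and 2 without triple mutant replicate 2 to 8 for the lower immune genes. The other lists of this paragraph that passed had adjusted p 0.445 to 0.722 with an estimated correlation.

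Of the other lists in triple mutant seedlings, 4 replication genes, 2 silencing genes, 2 photosynthesis genes and 2 root genes were higher and 2 clock genes higher and 3 lower. Without WT replicate 1 these numbered 0, 0, 1, 1, 1 and 1, and without pol2a-2 replicate 1 replication and silencing genes numbered 7 and 5. The 6 other tested lists had camera adjusted p 0.0592 to 0.791, the genes silenced by DNA methylation with a median of -0.43 and a camera direction of up. The largest rises and falls were in the repeated-sequence genes named for suvh2suvh9 and in chloroplast genes. In all 1404 genes were higher and 1257 lower, 119 and 12 with repeated sequence and 5 and 79 organellar. Higher genes numbered 343 and 518 without WT replicates 1 and 2, 2244 and 2119 without pol2a-2 replicates 1 and 2 and 462 and 594 without triple mutant replicates 1 and 2. Lower genes numbered 405 and 617 without WT replicates 1 and 2, 1932 and 2025 without pol2a-2 replicates 1 and 2 and 398 and 473 without triple mutant replicates 1 and 2. Calls ended for DMC1 without WT replicate 1, AP3 without either triple mutant replicate and COR15A without triple mutant replicate 1 (adjusted p 0.0526 to 0.0660).

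Among 1748 TEs tested in seedlings, 148 were higher and 100 lower in suvh2suvh9, and 203 and 98 in the triple mutant. Of these 110 and 64 were shared (17.2 and 5.61 expected from list sizes). These TE comparisons cross the library sets. Of the 148 higher TEs, the 82 tested in meiocytes had a median log2 fold change of 0.05 in suvh2suvh9 meiocytes. Higher and lower TEs numbered 15 and 16 in seedlings titled pol2a-2, 2 and 0 in pol2a-1, and in meiocytes 8 and 14 in pol2a-1, 4 and 5 in pol2a-2 and 1 and 0 in the triple mutant. TEs have no coordinates in the reference used here, so their repeated sequence could not be examined. With 1 library left out the higher TEs of suvh2suvh9 seedlings numbered 39 and 41 without WT replicates 1 and 2, 58 and 45 without suvh2suvh9 replicates 1 and 2 and 97 without triple mutant replicate 2, and the lower 24 and 47 without WT replicates 1 and 2 and 35 and 23 without suvh2suvh9 replicates 1 and 2. In triple mutant seedlings the higher TEs numbered 45 and 67 without WT replicates 1 and 2 and 60 and 67 without triple mutant replicates 1 and 2, and the lower 27 and 46 without WT replicates 1 and 2 and 19 and 31 without triple mutant replicates 1 and 2.

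The triple mutant was compared with suvh2suvh9, inside 1 library set, to ask what its pol2a mutation adds. DNA damage response genes were higher in the triple mutant, 7 of 24 over all genes and 16 adjusted over the list alone (median 1.27, camera adjusted p 2.0e-33), XRI1 3.85-fold (log2 1.94 ± 0.14, adjusted p 8.1e-04) and TSO2 4.12-fold (log2 2.04 ± 0.21, adjusted p 0.00625). Polycomb and flowering targets were higher, 6 of 19 and 10 adjusted over the list alone (median 1.39, camera adjusted p 2.8e-25), FT 18.7-fold (log2 4.23 ± 0.44, adjusted p 0.00730) and SEP1 23.6-fold (log2 4.56 ± 0.37, adjusted p 0.00145). All 5 tested genes silenced by DNA methylation were lower (median -1.24, 3 adjusted over the list alone, camera adjusted p 2.9e-04). These 3 lists had adjusted p 0.117 to 0.201 with an estimated correlation. The first 2 had 1 without suvh2suvh9 replicate 2 to 10 and 2 without triple mutant replicate 1 to 8 called genes with 1 library left out. In all 48 genes differed, 36 higher and 12 lower. This number was 16 without either WT replicate, 18 without either pol2a-1 replicate, 275 and 239 without pol2a-2 replicates 1 and 2, 217 and 8 without suvh2suvh9 replicates 1 and 2 and 11 and 21 without triple mutant replicates 1 and 2. Against pol2a-1, across the library sets, 2223 genes differed, of 986 higher 107 and of 1237 lower 11 with repeated sequence and 2 and 80 organellar. This number was 1481 without WT replicate 2, 832 and 577 without pol2a-1 replicates 1 and 2, 4551 and 4525 without pol2a-2 replicates 1 and 2 and 567 and 579 without triple mutant replicates 1 and 2. Non-additivity was called for 2 genes, and for 122 by DESeq2. Leaving out 1 library gave 0 without either WT replicate, 1 and 0 without pol2a-1 replicates 1 and 2, 55 and 58 without pol2a-2 replicates 1 and 2, 0 without suvh2suvh9 replicate 2 and 0 and 6 without triple mutant replicates 1 and 2.

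**Figure D4:**
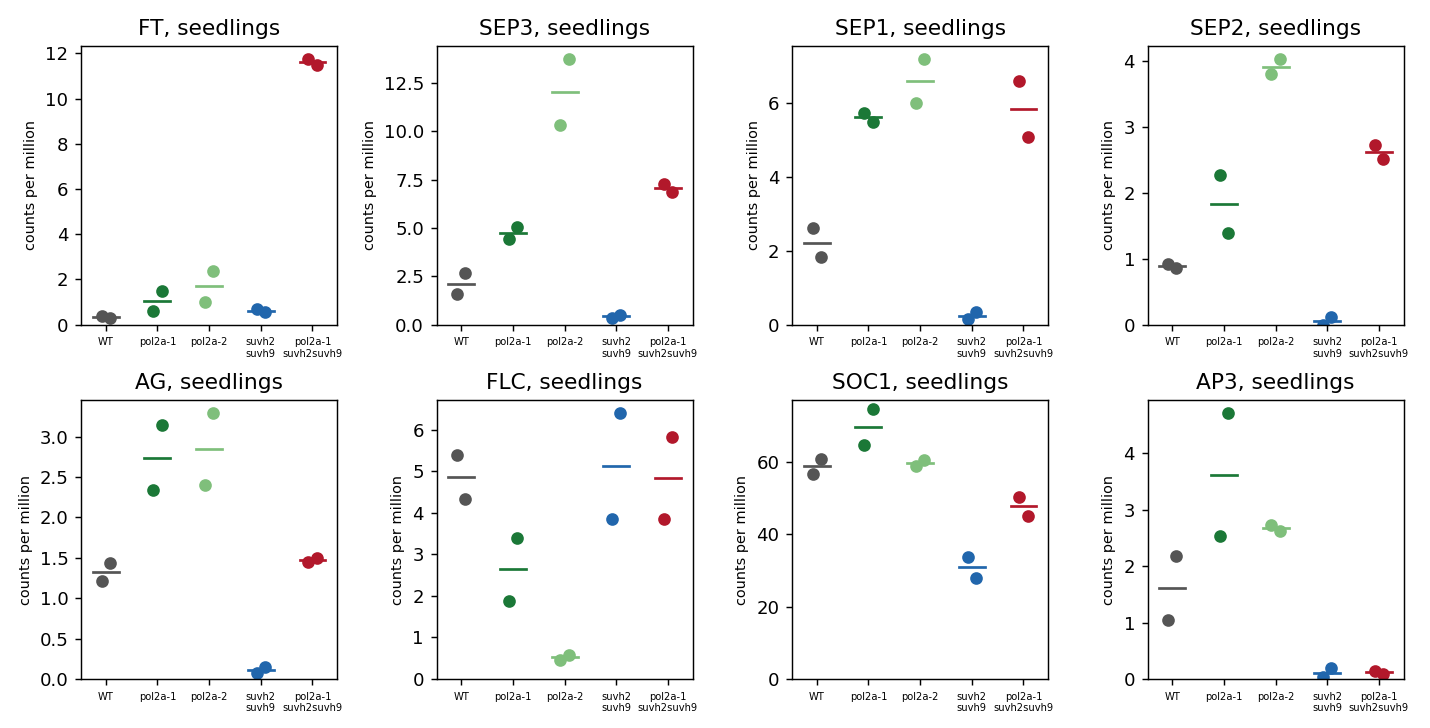
CPM of 8 flowering genes in each seedling library (points) with the group mean (line) by genotype. FT lies at 11.8 and 11.5 in the triple mutant and at 0.282 to 2.38 in the other libraries, and SEP1, SEP2, SEP3 and AG are lowest in suvh2suvh9.

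Changes against WT overlapped between mutants. Seedling suvh2suvh9 and triple mutant shared 730 higher and 754 lower genes (72.2 and 68.7 expected from list sizes). Outside repeated and organellar genes they shared 624 and 667. Their r was 0.76 (simulated 0.50, covariance 0.188 above the simulated). These groups form 1 library set and WT lies in the other. Seedling pol2a-2 and triple mutant shared 172 and 83 (24.7 and 11.8 expected, covariance 0.0667 above). Seedling pol2a-2 and suvh2suvh9 shared 52 and 59 (18.6 and 10.5 expected, covariance -0.0243 from simulated). The 52 became 2 and 9 without WT replicates 1 and 2, 90 and 223 without pol2a-2 replicates 1 and 2, 19 and 17 without suvh2suvh9 replicates 1 and 2 and 26 and 25 without triple mutant replicates 1 and 2. Part of each excess may come from the shared WT libraries or, in suvh2suvh9 and the triple mutant, the library sets.

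The last comparison, which crosses the library sets, asked whether a mutant's effect differs between tissues. In WT, 8021 genes were higher in meiocytes and 9479 in seedlings. All 41 meiosis genes, 20 of 22 replication genes and 11 of 18 tapetum genes were higher in meiocytes. All 10 photosynthesis genes and 12 of 13 immune genes were higher in seedlings. XRI1 responded less in meiocytes than in seedlings, by log2 -2.97 ± 0.24, adjusted p 9.4e-06 in pol2a-2 and -2.46 ± 0.24, adjusted p 1.9e-05 in the triple mutant. DMC1 in pol2a-2 differed by -1.98 ± 0.26, adjusted p 0.00106, and HEI10 in suvh2suvh9 by -4.54 ± 0.49, adjusted p 8.1e-05. The interaction of tissue and genotype passed for 110 genes in pol2a-1, or 307 without meiocyte WT replicate 2, 46 without meiocyte pol2a-1 replicate 2, 194 and 189 without meiocyte pol2a-2 replicates 1 and 2, 32 and 53 without seedling WT replicates 1 and 2 and 41 and 34 without seedling pol2a-1 replicates 1 and 2. It passed for 240 in pol2a-2, or 746 without meiocyte WT replicate 1, 697 without meiocyte pol2a-2 replicate 2, 76 and 100 without seedling WT replicates 1 and 2 and 448 without seedling pol2a-2 replicate 2. In suvh2suvh9 it passed for 205, or 453 without meiocyte WT replicate 2, 79 and 89 without seedling WT replicates 1 and 2 and 82 and 85 without seedling suvh2suvh9 replicates 1 and 2. In the triple mutant it passed for 871, or 1344 without meiocyte WT replicate 1, 1333 and 1319 without meiocyte pol2a-2 replicates 1 and 2, 564 and 494 without meiocyte triple mutant replicates 1 and 2, 293 and 401 without seedling WT replicates 1 and 2 and 250 and 333 without seedling triple mutant replicates 1 and 2.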

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

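The share of calls on chromosome 1 and the tests of strain sequence linked to pol2a-1, of plant background, of library sets against the DNA damage response and of the loss of POL2A or SUVH2 and SUVH9 against repeated genes were chosen after the result was seen. Results are listed where a mutant's effect passed the interaction test between tissues, given as the fitted log2 effect in meiocytes minus that in seedlings. With a group at the counting floor, as in AT2G11035, AT1G35320 and NAC085, it is not a measured size. For pol2a-1 they were AT2G11035 (-12.09), AT1G35320 (-10.07), AT2G13965 (-5.79), AT4G01595 (-5.10), AT2G10931 (-5.79) and AT5G22920 (-2.65), for pol2a-2 RPF1 (-3.76), PAI1 (-3.22), NAC085 (-11.32), AT2G18193 (-5.44), XRI1 (-2.97), TSO2 (-2.17), TK1A (-2.14), DMC1 (-1.98), HEI10 (-3.97), HOP2 (-1.95), MND1 (-1.58) and DRM1 (-5.61). For suvh2suvh9 they were AT1G24996 (-16.30), AT5G22430 (8.97), HEI10 (-4.54), SEP1 (3.80), AG (3.96) and HSP90.1 (1.88) and, among chloroplast genes, ATCG01130 (9.00), ATCG01120 (8.56), ATCG00220 (8.30) and ATCG01110 (6.50). For the triple mutant they were AT1G08270 (-2.53), POL2A (-1.52), AT1G24996 (-14.23), XRI1 (-2.46), TSO2 (-1.42), HEI10 (-3.29), MRD1 (-5.25), AGO6 (-1.74), MORC6 (-1.04), MCM3 (-1.07) and BGLU23 (-3.33), all more negative in meiocytes, ABCA10 (5.76), PERK13 (2.50), AT3G02640 (1.70), THI2.1 (7.82), AGP31 (2.66), LTP6 (1.38), BAM5 (8.31), AP3 (4.73) and PRR5 (2.31), more positive, and the chloroplast genes ATCG01120 (9.54), ATCG01130 (9.33), ATCG00220 (7.98), ATCG01010 (8.20) and ATCG00800 (7.50). In all 110, 240, 205 and 871 genes passed for these 4 mutants, and 84 for suvh2suvh9 with repeated-sequence and organellar genes left out. Every effect crosses the library sets in 1 tissue, so no value here is of genotype alone. Those of chloroplast genes and AT1G24996 cannot be read as effects of genotype.

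Genes of repeated sequence were counted higher in meiocyte pol2a-1 and pol2a-2 and in seedling suvh2suvh9 and triple mutant libraries than in the others: those with at least 50% summed to 2456 to 2637 CPM in meiocyte WT and 6660 to 7251 in pol2a-1, and to 1130 to 1259 in seedling WT and 4083 to 4397 in suvh2suvh9. Loss of POL2A is argued against: the genes higher in pol2a-1 meiocytes had a median log2 fold change of 0 in the triple mutant, which carries pol2a-1, against 7.33 in pol2a-1. Loss of SUVH2 and SUVH9 is argued against too, as the genes higher in suvh2suvh9 seedlings had a median of 0 in suvh2suvh9 meiocytes and 3.42 in seedlings. Counting of reads shared between near-identical copies in some library sets fits: of the genes higher in meiocyte pol2a-1, 42 of 47 (89.4%) were higher in seedling suvh2suvh9, against 112 of all 352 repeated-sequence genes (31.8%) and 5.14% of all genes. A difference in processing between sets may explain it; the step is not known.

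Genes called in the pol2a meiocyte libraries outside repeated sequence lay in parts of the genome. In pol2a-2, 14 of 32 calls lay in the first 5 Mb of chromosome 1, with POL2A and 6.04% of tested genes (Fisher p 1.4e-09). In seedlings 46 of 539 did (8.53% against 5.95% tested, Fisher p 0.00884). Sequence of another strain around POL2A in pol2a-2 stays open: 25 of 38 genes there moved the same way in both tissues and 171 of 300 elsewhere (one-sided Fisher exact p 0.196). For pol2a-1, 4 of 52 (7.69%, upper 95% bound 18.5%) lay in that segment (Fisher p 0.386) and 30 on chromosome 1. Most calls lay outside that segment, but longer linked sequence stays open. A strain background of the meiocyte pol2a-1 plants stays open: 42 of the 52 had another within 1 Mb (32.3 on average in 10000 permutations, one-sided permutation p 0.00470). Signed by each gene's call, their median log2 fold change was 2.24 in the comparison that chose them. It was 0.0960 in seedlings labelled pol2a-1 and 0.53 in triple mutant meiocytes. There 4 were higher and 2 lower too, while 27 differed from pol2a-1.

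DNA damage response genes were higher in seedling pol2a-2 and triple mutant libraries and not called in pol2a-1 over all genes. The trend of counts with gene length is argued against, as the median in pol2a-2 was 2.04 with the trend removed and 16 of 24 genes were higher. The split of seedling library sets is argued against in the triple mutant, whose median against suvh2suvh9, in the same set, was 1.275 with 22 of 24 positive. Whether the seedling libraries titled pol2a-1 hold WT plants cannot be told apart from a weak allele effect: POL2A was at log2 0.24 ± 0.19 with the trend removed and -0.58 ± 0.27 without, though AT1G75945 was raised in pol2a-1 seedlings. Compared directly, 9 of 24 of these genes were higher in pol2a-2 than in pol2a-1.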

How the results depend on the processing

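The tests on repeated-sequence and organellar genes, on the length trend, on the pair of seedling libraries left out together and on the tissue differences with 1 library left out were chosen after the result was seen. Each value below is followed in brackets by the value in the report, and a count is listed where it moved by more than 1.5 times. The cause was not tested except where the construction of an alternative shows it. No called named gene changed its direction under any alternative run. Genes without a call were not followed throughout. Of 176 named gene results, 87 stayed called under every alternative run. Calls ended for 3 of them with DESeq2 size factors, 6 with the DESeq2 Wald test, 1 without the filter, 46 in the fit of all 20 libraries, 29 with only the groups compared, 7 without the length trend, 24 with a replicate block, 5 without organellar genes, 2 without the pair of seedling libraries and 6 without repeated-sequence and organellar genes. Whether depth limited the calls on weak genes was not tested. As a counting floor, 3 counts in a library stood for 0.0871 to 0.252 CPM.

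Scaling by DESeq2 size factors in place of TMM moved few values. Meiocyte triple mutant had 5 (8) genes higher. Seedling pol2a-1 had 1 (2) TEs higher.

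A 2-fold limit on shared genes moved 1 value. pol2a-2 and suvh2suvh9 shared 8 (52) higher genes in seedlings.

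Leaving out chloroplast and mitochondrial genes removed genes from the fit. Meiocyte pol2a-2 had 73 (114) genes higher. Meiocyte triple mutant had 5 (8) genes higher. In meiocytes triple mutant against suvh2suvh9 gave 1 (8) and non-additivity gave 22 (35) genes.

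Leaving out repeated-sequence and organellar genes also ended calls of other genes. pol2a-1 meiocytes had 16 (84) genes higher and 9 (14) TEs lower. pol2a-2 meiocytes had 3 (114) genes higher, 3 (14) lower, 2 (4) TEs higher and 1 (5) lower. For meiocytes, triple mutant against pol2a-1 gave 43 (127), triple mutant against suvh2suvh9 gave 1 (8), pol2a-2 against pol2a-1 gave 49 (92) and non-additivity gave 7 (35) genes. pol2a-1 and pol2a-2 shared 0 (60) higher genes in meiocytes. pol2a-1 seedlings had 1 (2) TEs higher. The tissue difference held 84 genes (205) for suvh2suvh9.

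Removing the trend with gene length gave these values. Meiocyte pol2a-2 had 9 (14) genes lower and 2 (5) TEs lower. Meiocyte triple mutant had 3 (8) genes higher and 0 (1) TEs higher. In meiocytes triple mutant against suvh2suvh9 gave 5 (8) genes. Gene list tests passed 18 times (28) in meiocytes. Seedling pol2a-2 had 602 (361) genes higher, 368 (193) lower and 29 (16) TEs lower. In seedlings triple mutant against suvh2suvh9 gave 137 (48) and pol2a-2 against pol2a-1 gave 164 (82) genes. pol2a-2 and suvh2suvh9 shared 94 (52) higher genes in seedlings.

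Treating pol2a-1 and pol2a-2 as 1 group of 4, as their genotype label reads, gave these values. pol2a-1 meiocytes had 55 (84) genes higher, 0 (31) lower, 4 (8) TEs higher and 1 (14) lower. pol2a-2 meiocytes had 55 (114) genes higher, 0 (14) lower and 1 (5) TEs lower. pol2a-1 seedlings had 1 (3) genes higher and 3 (1) lower. pol2a-2 seedlings had 1 (361) genes higher, 3 (193) lower, 2 (15) TEs higher and 0 (16) lower.

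Leaving out seedling pol2a-1 replicate 2 and pol2a-2 replicate 1 together, the 2 seedling libraries with the steepest length trend, left a lone library in both groups. Seedling pol2a-1 had 11 (3) genes higher and 9 (1) lower. Seedling pol2a-2 had 26 (15) TEs higher. Seedling suvh2suvh9 had 2089 (1057) genes higher, 2039 (1123) lower, 253 (148) TEs higher and 157 (100) lower. Seedling triple mutant had 2476 (1404) genes higher, 2297 (1257) lower, 337 (203) TEs higher and 169 (98) lower. In seedlings triple mutant against suvh2suvh9 gave 292 (48), pol2a-2 against pol2a-1 gave 195 (82) and non-additivity gave 10 (2) genes. pol2a-1 and pol2a-2 shared 5 (1), pol2a-1 and suvh2suvh9 shared 6 (2) and pol2a-2 and suvh2suvh9 shared 125 (52) higher genes in seedlings.

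Without the low-count filter the values were these. pol2a-1 meiocytes had 270 (84) genes higher, 298 (31) lower, 21 (8) TEs higher and 41 (14) lower. pol2a-2 meiocytes had 363 (114) genes higher, 105 (14) lower, 14 (4) TEs higher and 17 (5) lower. suvh2suvh9 meiocytes had 100 (0) genes higher, 199 (1) lower, 6 (0) TEs higher and 5 (0) lower. Triple mutant meiocytes had 569 (8) genes higher, 236 (4) lower, 21 (1) TEs higher and 16 (0) lower. For meiocytes, triple mutant against pol2a-1 gave 1107 (127), triple mutant against suvh2suvh9 gave 406 (8), pol2a-2 against pol2a-1 gave 1005 (92) and non-additivity gave 390 (35) genes. pol2a-1 and pol2a-2 shared 130 (60), pol2a-1 and suvh2suvh9 shared 31 (0) and pol2a-2 and suvh2suvh9 shared 16 (0) higher genes in meiocytes. pol2a-1 seedlings had 317 (3) genes higher, 1286 (1) lower, 30 (2) TEs higher and 99 (0) lower. pol2a-2 seedlings had 1003 (361) genes higher, 1571 (193) lower, 71 (15) TEs higher and 89 (16) lower. suvh2suvh9 seedlings had 1664 (1057) genes higher, 235 (148) TEs higher and 152 (100) lower. Triple mutant seedlings had 1947 (1257) genes lower and 157 (98) TEs lower. For seedlings, triple mutant against pol2a-1 gave 4101 (2223), triple mutant against suvh2suvh9 gave 985 (48), pol2a-2 against pol2a-1 gave 844 (82) and non-additivity gave 728 (2) genes. pol2a-1 and pol2a-2 shared 139 (1), pol2a-1 and suvh2suvh9 shared 107 (2) and pol2a-2 and suvh2suvh9 shared 156 (52) higher genes in seedlings. The tissue difference held 721 genes (110) for pol2a-1, 1167 genes (240) for pol2a-2, 854 genes (205) for suvh2suvh9 and 2101 genes (871) for the triple mutant.

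The DESeq2 Wald test gave these values. Meiocyte pol2a-1 had 209 (84) genes higher, 105 (31) lower, 15 (8) TEs higher and 31 (14) lower. Meiocyte pol2a-2 had 264 (114) genes higher, 58 (14) lower, 11 (4) TEs higher and 9 (5) lower. Meiocyte suvh2suvh9 had 68 (0) genes higher, 112 (1) lower, 4 (0) TEs higher and 3 (0) lower. Meiocyte triple mutant had 409 (8) genes higher, 78 (4) lower, 17 (1) TEs higher and 8 (0) lower. In meiocytes triple mutant against pol2a-1 gave 553 (127), triple mutant against suvh2suvh9 gave 165 (8), pol2a-2 against pol2a-1 gave 512 (92) and non-additivity gave 140 (35) genes. pol2a-1 and pol2a-2 shared 103 (60), pol2a-1 and suvh2suvh9 shared 18 (0) and pol2a-2 and suvh2suvh9 shared 7 (0) higher genes in meiocytes. Seedling pol2a-1 had 57 (3) genes higher, 67 (1) lower and 5 (0) TEs lower. Seedling pol2a-2 had 591 (361) genes higher, 426 (193) lower, 30 (15) TEs higher and 29 (16) lower. In seedlings triple mutant against suvh2suvh9 gave 358 (48), pol2a-2 against pol2a-1 gave 262 (82) and non-additivity gave 122 (2) genes. pol2a-1 and pol2a-2 shared 25 (1) and pol2a-1 and suvh2suvh9 shared 27 (2) higher genes in seedlings. The tissue difference held 401 genes (110) for pol2a-1, 942 genes (240) for pol2a-2, 709 genes (205) for suvh2suvh9 and 2123 genes (871) for the triple mutant.

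A single fit of all 20 libraries shared the spread over both tissues. pol2a-1 meiocytes had 297 (84) genes higher, 76 (31) lower and 18 (8) TEs higher. pol2a-2 meiocytes had 417 (114) genes higher, 48 (14) lower, 14 (4) TEs higher and 8 (5) lower. suvh2suvh9 meiocytes had 108 (0) genes higher, 50 (1) lower and 7 (0) TEs higher. Triple mutant meiocytes had 1044 (8) genes higher, 123 (4) lower, 36 (1) TEs higher and 12 (0) lower. For meiocytes, triple mutant against pol2a-1 gave 483 (127), triple mutant against suvh2suvh9 gave 136 (8), pol2a-2 against pol2a-1 gave 322 (92) and non-additivity gave 85 (35) genes. pol2a-1 and pol2a-2 shared 143 (60), pol2a-1 and suvh2suvh9 shared 66 (0) and pol2a-2 and suvh2suvh9 shared 35 (0) higher genes in meiocytes. pol2a-1 seedlings had 0 (3) genes higher, 0 (1) lower and 0 (2) TEs higher. pol2a-2 seedlings had 107 (361) genes higher, 25 (193) lower, 2 (15) TEs higher and 5 (16) lower. suvh2suvh9 seedlings had 260 (1057) genes higher, 265 (1123) lower, 33 (148) TEs higher and 10 (100) lower. Triple mutant seedlings had 417 (1404) genes higher, 302 (1257) lower, 44 (203) TEs higher and 12 (98) lower. For seedlings, triple mutant against pol2a-1 gave 663 (2223), triple mutant against suvh2suvh9 gave 20 (48), pol2a-2 against pol2a-1 gave 48 (82) and non-additivity gave 0 (2) genes. pol2a-1 and pol2a-2 shared 0 (1), pol2a-1 and suvh2suvh9 shared 0 (2) and pol2a-2 and suvh2suvh9 shared 10 (52) higher genes in seedlings.

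Fitting only the groups compared estimated the spread from fewer libraries. Meiocyte pol2a-1 had 8 (14) TEs lower. Meiocyte pol2a-2 had 3 (14) genes lower and 1 (5) TEs lower. Meiocyte suvh2suvh9 had 3 (0) genes higher and 77 (1) lower. Meiocyte triple mutant had 1 (8) genes higher, 0 (4) lower and 0 (1) TEs higher. In meiocytes triple mutant against pol2a-1 gave 3752 (127) and triple mutant against suvh2suvh9 gave 0 (8) genes. Seedling pol2a-1 had 341 (3) genes higher, 1040 (1) lower, 9 (2) TEs higher and 48 (0) lower. Seedling pol2a-2 had 70 (361) genes higher, 55 (193) lower, 2 (15) TEs higher and 6 (16) lower. Seedling suvh2suvh9 had 1691 (1057) genes higher and 1692 (1123) lower. Seedling triple mutant had 2599 (1404) genes higher, 2649 (1257) lower and 189 (98) TEs lower. In seedlings triple mutant against pol2a-1 gave 3768 (2223), pol2a-2 against pol2a-1 gave 8 (82) and non-additivity gave 47 (2) genes. pol2a-1 and pol2a-2 shared 14 (1), pol2a-1 and suvh2suvh9 shared 111 (2) and pol2a-2 and suvh2suvh9 shared 17 (52) higher genes in seedlings.

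The gene list tests were repeated with an estimated correlation and with fry, which tests whether the genes of a list move, on balance, 1 way. With an estimated correlation they passed 0 times (28) in meiocytes and 0 times (37) in seedlings. With fry they passed 0 times (28) in meiocytes and 9 times (37) in seedlings.

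The replicate numbers did not pair the samples. Across genes, the difference between replicates 1 and 2 was correlated by more than 0.1 in 2 of 10 pairs of meiocyte groups (-0.41 to 0.37) and in 3 of 10 pairs of seedling groups (-0.41 to 0.31). With the number fitted as a replicate block, counts moved as follows. pol2a-2 meiocytes had 9 (14) genes lower. suvh2suvh9 meiocytes had 2 (1) genes lower. Triple mutant meiocytes had 0 (1) TEs higher. pol2a-1 seedlings had 0 (3) genes higher, 0 (1) lower and 1 (2) TEs higher. pol2a-2 seedlings had 226 (361) genes higher, 99 (193) lower and 7 (15) TEs higher. For seedlings, triple mutant against suvh2suvh9 gave 17 (48), pol2a-2 against pol2a-1 gave 41 (82) and non-additivity gave 0 (2) genes. pol2a-1 and pol2a-2 shared 0 (1), pol2a-1 and suvh2suvh9 shared 0 (2) and pol2a-2 and suvh2suvh9 shared 33 (52) higher genes in seedlings. With the block within each tissue, the tissue difference held 73 genes (110) for pol2a-1 and 128 genes (205) for suvh2suvh9.

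Each library was left out in turn, which left 1 library in its group; that lone library is assumed to vary like the other groups. The libraries that moved a count by more than 1.5 times are named in the report or in brackets here. Meiocyte genes higher ranged over 56 to 154 (84) in pol2a-1, 68 to 139 (114) in pol2a-2, 0 to 15 (0) in suvh2suvh9 and 3 to 47 (8) in triple mutant. Meiocyte genes lower ranged over 11 to 85 (31) in pol2a-1, 7 to 30 (14) in pol2a-2, 1 to 57 (1) in suvh2suvh9 and 2 to 17 (4) in triple mutant. Meiocyte genes changed ranged over 79 to 238 (127) in triple mutant against pol2a-1, 1 to 15 (8) in triple mutant against suvh2suvh9, 22 to 255 (92) in pol2a-2 against pol2a-1 and 16 to 41 (35) in non-additivity. Meiocyte shared genes higher ranged over 48 to 71 (60) in pol2a-1 and pol2a-2, 0 to 3 (0) in pol2a-1 and suvh2suvh9 (1 without WT replicate 1, 3 without either pol2a-2 replicate and 1 without suvh2suvh9 replicate 2) and 0 to 1 (0) in pol2a-2 and suvh2suvh9 (1 without WT replicate 1 and 1 without pol2a-2 replicate 2). In seedlings the 2 libraries titled pol2a-2 were less alike than those of any other seedling group, and leaving out either raised most counts. Seedling genes higher ranged over 0 to 301 (3) in pol2a-1, 31 to 1691 (361) in pol2a-2, 300 to 1786 (1057) in suvh2suvh9 and 343 to 2244 (1404) in triple mutant. Seedling genes lower ranged over 0 to 745 (1) in pol2a-1, 7 to 2302 (193) in pol2a-2, 360 to 1776 (1123) in suvh2suvh9 and 398 to 2025 (1257) in triple mutant. Seedling genes changed ranged over 567 to 4551 (2223) in triple mutant against pol2a-1, 8 to 275 (48) in triple mutant against suvh2suvh9, 9 to 875 (82) in pol2a-2 against pol2a-1 and 0 to 58 (2) in non-additivity. Seedling shared genes higher ranged over 0 to 208 (1) in pol2a-1 and pol2a-2 (0 without WT replicate 1, 0 without either pol2a-1 replicate, 42 and 208 without pol2a-2 replicates 1 and 2 and 0 without either triple mutant replicate), 0 to 103 (2) in pol2a-1 and suvh2suvh9 (0 without either WT replicate, 0 without either pol2a-1 replicate, 102 and 103 without pol2a-2 replicates 1 and 2, 0 without either suvh2suvh9 replicate and 1 without either triple mutant replicate) and 2 to 223 (52) in pol2a-2 and suvh2suvh9. Genes differing between tissues ranged over 32 to 307 (110) in pol2a-1, 76 to 746 (240) in pol2a-2, 79 to 453 (205) in suvh2suvh9 and 250 to 1344 (871) in the triple mutant.

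Meiocyte TEs higher ranged over 3 to 8 (8) in pol2a-1 (5 without WT replicate 1 and 3 without pol2a-1 replicate 1), 2 to 6 (4) in pol2a-2 (2 without either WT replicate and 2 without pol2a-1 replicate 1), 0 to 2 (0) in suvh2suvh9 (1 without either pol2a-2 replicate and 2 without suvh2suvh9 replicate 2) and 0 to 5 (1) in triple mutant (0 without either WT replicate, 4 and 5 without pol2a-2 replicates 1 and 2, 3 without either suvh2suvh9 replicate and 0 without triple mutant replicate 2). Meiocyte TEs lower ranged over 6 to 21 (14) in pol2a-1 (7 without WT replicate 1, 6 and 8 without pol2a-1 replicates 1 and 2 and 9 without triple mutant replicate 2), 2 to 6 (5) in pol2a-2 (2 and 3 without WT replicates 1 and 2 and 3 and 2 without pol2a-2 replicates 1 and 2), 0 to 0 (0) in suvh2suvh9 and 0 to 1 (0) in triple mutant (1 without WT replicate 2). Seedling TEs higher ranged over 0 to 12 (2) in pol2a-1 (0 and 1 without WT replicates 1 and 2, 0 and 1 without pol2a-1 replicates 1 and 2, 12 without either pol2a-2 replicate, 1 without either suvh2suvh9 replicate and 1 without either triple mutant replicate), 2 to 51 (15) in pol2a-2 (2 and 3 without WT replicates 1 and 2, 51 without pol2a-2 replicate 2 and 6 without either triple mutant replicate), 39 to 214 (148) in suvh2suvh9 and 45 to 284 (203) in triple mutant. Seedling TEs lower ranged over 0 to 42 (0) in pol2a-1 (42 and 38 without pol2a-2 replicates 1 and 2), 4 to 132 (16) in pol2a-2 (4 and 6 without WT replicates 1 and 2, 132 without pol2a-2 replicate 2 and 10 without either triple mutant replicate), 23 to 139 (100) in suvh2suvh9 and 19 to 143 (98) in triple mutant.

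Among the named genes, the number that stayed called against WT with any 1 library left out was 12 of 16 in meiocyte pol2a-1, 3 of 10 in meiocyte triple mutant, 9 of 16 in meiocyte pol2a-2, 1 of 1 in meiocyte suvh2suvh9, 0 of 4 in seedling pol2a-1, 33 of 55 in seedling triple mutant, 9 of 32 in seedling pol2a-2 and 32 of 42 in seedling suvh2suvh9.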
